A study of Mus musculus with 16 samples.

How the data were processed

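Serum was taken from male mice aged 4, 8, 36 and 58 weeks, with 4 separate mice at each age per the labels. RNA from each serum, 1 ng as input per the labels' protocols, was labelled with a single dye (Cy3) and hybridized to an Agilent mouse miRNA microarray. Each of the 16 arrays holds 58594 spots. The mouse miRNAs on it number 1881 and are read by 4415 probes, each spotted several times.

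The deposited files are scanner output, 1 per array, and their spot intensities were made with Agilent Feature Extraction version 11.5 per the submitters' processing notes (11.5.1.1 per the file headers). The background-subtracted intensity of each spot, the total signal of each miRNA, the flags for outlier and saturated spots and the detection call of each miRNA are the authors' deposited values. No scaling between arrays is recorded in the file headers. No spot was saturated on any array. Between 2.32% and 4.48% of miRNA spots per array carried an outlier flag.

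From there, spots with an outlier flag were left out and the processed intensity was averaged over the spots of a probe and then over the probes of a miRNA. Each array was scaled so that the 75th percentile over the 24 miRNAs detected on all 16 arrays was equal. Scaled values below 3.79, the median over arrays of the lowest scaled signal of a detected miRNA, were set to that floor, and log2 was taken. A miRNA was tested if it was detected on at least 3 of the 4 arrays of at least 1 age, which left 285. Where a miRNA was detected on no array of an age, its fold is given as a bound ("at least N-fold"). That bound sets the mean of the brighter age against the mean of, per array, the highest of the lowest signal of a detected miRNA, the miRNA's own signal and the floor. The mean of the brighter age takes in its arrays without detection, so the bound is approximate where there are any. Fitted log2 differences and slopes of such a miRNA depend on the floor and are no bound.

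Ages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per age over all 16 arrays: a moderated F test for any difference, the slope per doubling of age, and the 6 pairs of ages. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. All adjusted p-values for miRNAs are from limma. Gene lists with at least 3 tested members (12 of the 15 lists) were tested with limma's camera at its preset correlation of 0.01, with camera's estimated correlation and fry beside it. The lists covered erythrocyte, platelet and endothelial, leukocyte, liver, striated muscle, brain, epithelial (with gut and pancreas), testis, Dlk1-Dio3 cluster, let-7, miR-17 cluster with its paralogs, miR-29 and miR-30, ageing and inflammation, Sfmbt2 cluster and late miRBase miRNAs, the last being those numbered 5000 or higher. Measures with 1 value per array were compared by 2-sided exact permutation tests over the 70 assignments of 8 arrays, whose smallest p is 0.0286. Adjusted over the 6 pairs, at least 4 of them must reach it for any to pass, so that these tests show no absence of a difference. Groups, tests, lists and most alternatives were fixed before the data were examined.

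The miRNAs named are the 12 with the smallest p in each direction among those that passed in a comparison, and the 5 with the smallest p where fewer than 5 passed. Members of a list are named as examples by the smallest p, at most 4 per list.

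Per the file headers the arrays lay on 2 slides. Slide 1 held all arrays of 4 and 8 weeks and slide 2 all arrays of 36 and 58 weeks. The comparisons of 8 with 4 weeks and of 58 with 36 weeks lie within a slide. In the other 4 pairs age and slide cannot be told apart. Feature Extraction marked 3 arrays for evaluation: 4-week replicates 1 and 4 and 36-week replicate 4. All were kept.

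The tests were tried on simulated data with the measured spread, 57 of the 285 miRNAs changed per run over 20 runs. For 58 against 4 weeks, 7.63% of changes of 1 on the log2 scale were recovered, 37.9% of changes of 2 and 63.7% of changes of 3. For the trend, changes of the same sizes from 4 to 58 weeks were recovered at 14.2%, 48.2% and 77.4%. A list of 8 members raised by 2 was found in 20 of 20 runs, with 2 calls of unchanged lists. The simulated miRNAs varied independently of each other, while on the real arrays the first principal component held 79.9% of the variance. These recovery rates thus may not carry over to the data.

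Alternatives covered the scaling, quantile normalization, the deposited total signal, normexp background correction, the detection filter, the floor, the choice of probe, the variance model, array weights, blocks for slide and replicate number, the arrays in the fit and leaving out each array. The normexp alternative used the median spot signal in place of the mean, which was not used here. It also added an offset of 50 to each signal, which shrinks the log2 differences of dim miRNAs. In addition, 3 alternatives were added after seeing the data and are named where they appear. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.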

Results

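Circulating miRNAs were measured in the serum of male mice at 4, 8, 36 and 58 weeks of age, 4 mice per age, to ask which of them change as mice grow and age. Of 1881 mouse miRNAs on the array, 572 were detected on at least 1 of the 16 arrays, 24 on all of them and 1309 on none. The mean number detected per array was 290 ± 50.1 (SD, n = 4) at 4 weeks, 217 ± 23.8 at 8 weeks, 226 ± 61.8 at 36 weeks and 219 ± 47.6 at 58 weeks. The smallest p of the 6 pairs of ages was 0.0571 for 8 against 4 weeks (2-sided exact permutation, adjusted p = 0.343), in a test that a single pair cannot pass after adjustment.

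The arrays differed widely in background. The SD of the negative-control spots was 59.3 on 36-week replicate 4, 19.1 on 4-week replicate 1 and 7.45 on 4-week replicate 4, against at most 4.45 on the others. The first principal component over the 285 tested miRNAs held 79.9% of the variance. Its size followed the log2 of this SD across the 16 arrays (Pearson r = 0.940, Spearman rho = 0.941, each permutation p = 1e-05, the smallest that 100000 permutations can give). Without the 2 arrays farthest from the median SD, r was 0.863, and within slides it was 0.976 on slide 1 and 0.938 on slide 2 (8 arrays each).

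**Figure D1:**
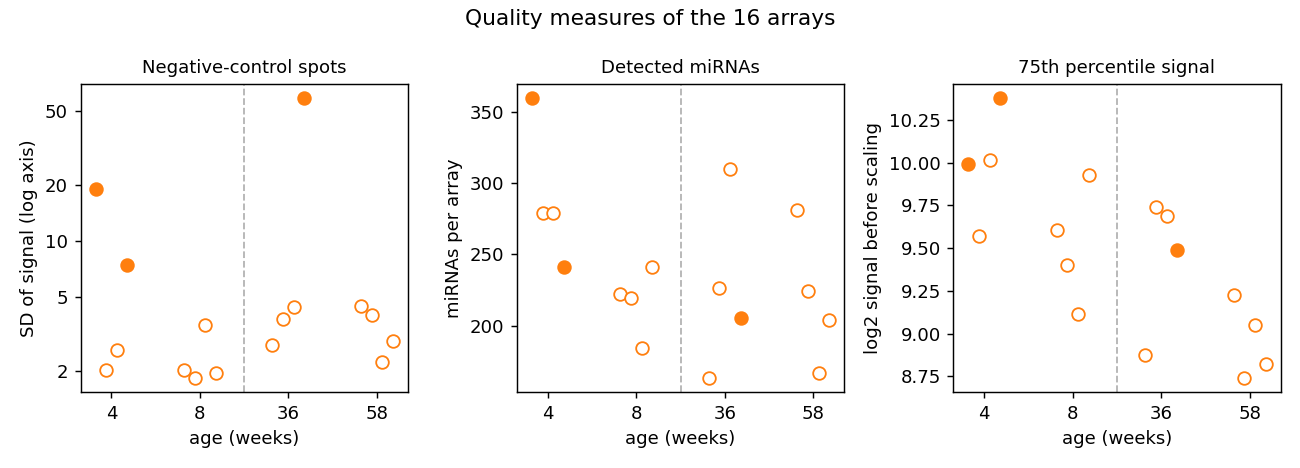
Quality measures of each array by age in weeks: SD of the negative-control spots (log axis), number of detected miRNAs, and log2 of the 75th percentile signal before scaling. Filled points are the 3 arrays marked for evaluation by the scanner software, and the dashed line parts slide 1 (4 and 8 weeks) from slide 2 (36 and 58 weeks); the highest SD, 59.3, is on 36-week replicate 4.

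A measure of red cell RNA, log2 of erythrocyte miR-451a minus log2 of miR-23a-3p, was 3.35 ± 0.74 (SD, n = 4) at 4 weeks, 2.89 ± 0.62 at 8 weeks, 3.26 ± 0.90 at 36 weeks and 2.73 ± 0.24 at 58 weeks. It was 0.62 lower at 58 than at 4 weeks, the pair with the smallest p (exact permutation p = 0.2, adjusted p = 0.771), in the same kind of test. The 75th percentile signal before scaling was 9.99 ± 0.33 on the log2 scale at 4 weeks, 9.51 ± 0.34 at 8 weeks, 9.45 ± 0.40 at 36 weeks and 8.96 ± 0.22 at 58 weeks. It was 2.04-fold lower at 58 than at 4 weeks, a difference that did not pass correction (exact permutation p = 0.0286, adjusted p = 0.103). Within slides the differences were -0.48 for 8 against 4 weeks and -0.49 for 58 against 36 weeks (exact permutation p = 0.0857 for each).

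Across all 4 ages, miR-214-3p, which is made from an antisense transcript of the Dnm3 gene together with miR-199a, was the 1 miRNA that passed. Its fitted slope was -0.75 ± 0.12 (SE) on the log2 scale per doubling of age (adjusted p = 0.00175), and it also passed the F test for any difference (adjusted p = 0.0431). Its log2 signal was 4.78 ± 0.62 (SD, n = 4) at 4 weeks and 3.64 ± 1.18 at 8 weeks, with detection on 3 of 4 arrays at each. It was detected on 0 of 4 arrays at 36 weeks and on 0 of 4 at 58 weeks, so the size of the slope depends on the floor. With a lower floor, among the alternatives fixed beforehand, the slope was -1.19 (adjusted p = 0.000232). At or near the floor the SD was 0.14 at 36 weeks and 0 at 58 weeks, which understates the spread. The SE and adjusted p of miR-214-3p, here and in the pairs of ages below, may thus be too small. Both of its probes had lower signals at older ages, with slopes of -0.89 and -0.38. With slide as a block the slope of miR-214-3p was -0.83 ± 0.44 (SE, unadjusted p = 0.0746 in limma), and no miRNA passed the trend or the F test. Its slope was -0.41 under quantile normalization (adjusted p = 0.284) and -0.58 with the deposited total signal of each miRNA (adjusted p = 0.0939). With normexp background correction it was -0.0064 (adjusted p = 0.878), and none of these passed.

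The other miRNAs with the smallest p for the trend did not pass. Lower values with age were measured for the cartilage-enriched miR-140-3p (slope -0.69 ± 0.18 SE, adjusted p = 0.130), miR-199a-3p (slope -0.56 ± 0.15, adjusted p = 0.130) and miR-181b-5p (slope -0.53 ± 0.15, adjusted p = 0.159). The last was detected on 2 of 4 arrays at 4 weeks, on 3 of 4 at 8 weeks and on no array at 36 or 58 weeks. Without 36-week replicate 4, miR-140-3p and miR-199a-3p passed the trend (adjusted p = 0.00276 and 0.0250). The p53-induced miR-34a-5p had a slope of 0.36 ± 0.11 (adjusted p = 0.237). Its slope kept its sign in 29 of 30 alternatives and was -0.45 in the other, with slide as a block. Within slides miR-34a-5p differed by -0.68 for 8 against 4 weeks and by 0.03 for 58 against 36 weeks. Its rise thus lay in the step from 8 to 36 weeks, where age and slide cannot be told apart. The slope of miR-181b-5p kept its sign in 26 of 27 and was 0.04 in the other. The slope of miR-199a-3p was negative in all 30, with -0.015 nearest to no change. In the F test miR-199a-3p, miR-34a-5p and miR-181b-5p each had an adjusted p of 0.305, and miR-375-3p, a miRNA of pancreatic islet and gut epithelium, one of 0.445. In all, 25 miRNAs had an unadjusted p under 0.05 for the trend and 13 for the F test, where 14.3 would by chance. With 1 array left out the trend count ran from 11 (8-week replicate 2) to 66 (4-week replicate 1). That of the F test ran from 8 (8-week replicate 1) to 22 (36-week replicate 4).

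**Figure D2:**
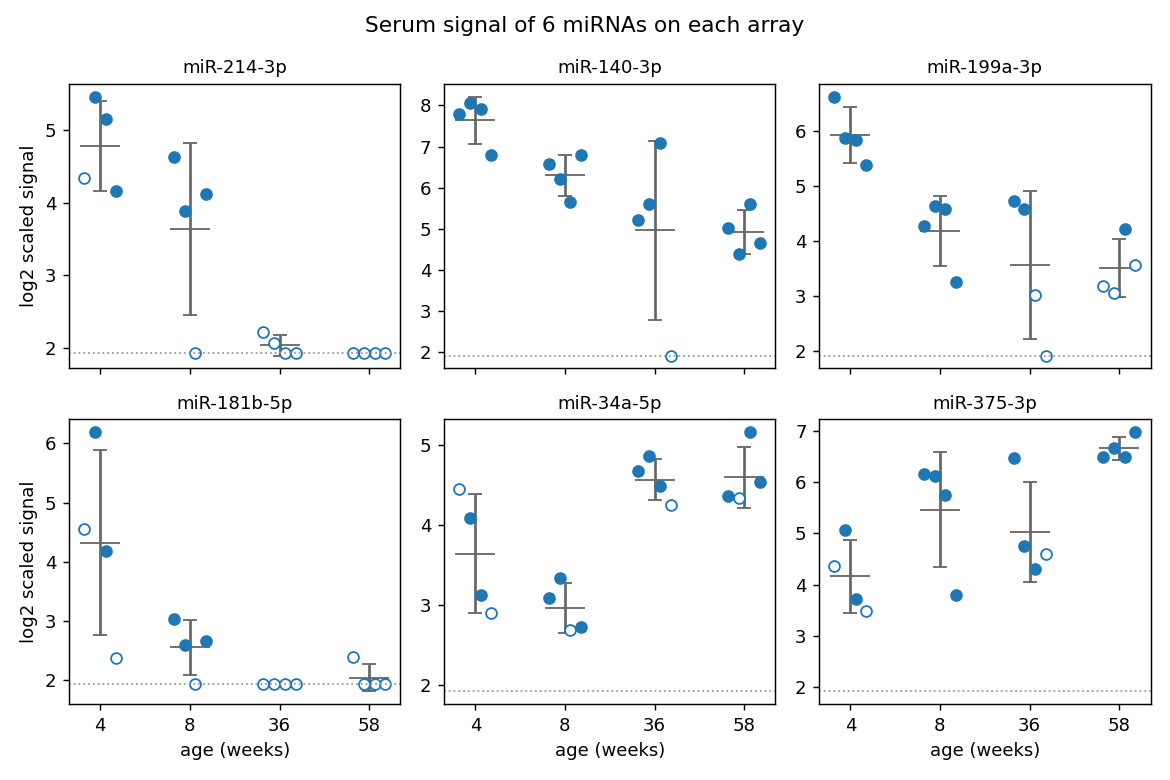
Log2 scaled signal of 6 miRNAs on each array against age in weeks. Filled points are arrays on which the miRNA was detected and open points arrays on which it was not; grey bars are the mean and SD of 4 arrays, and the dotted line is the floor. At 36 and 58 weeks miR-214-3p was detected on 0 of 4 arrays.

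Between 8 and 4 weeks, ages that share slide 1 and span puberty, 0 of 285 miRNAs passed (limma, 6 with an unadjusted p under 0.05, all lower at 8 weeks). The 5 with the smallest p were miR-181b-5p, miR-199a-3p, miR-140-5p, miR-199b-5p and miR-30b-5p, each with an adjusted p of 0.536. Their log2 differences were -1.77 ± 0.61 (SE), -1.74 ± 0.61, -2.05 ± 0.75, -1.53 ± 0.62 and -1.28 ± 0.56. That of miR-181b-5p was -1.14 without 4-week replicate 2 and -2.41 without 4-week replicate 4, and that of miR-140-5p -1.31 without 8-week replicate 4. Under quantile normalization the 5 differences were, in the same order, -0.02, -0.27, -0.59, 0.06 and 0.07. The median difference over the tested miRNAs was -0.72, and 0.20 under quantile normalization. It was -0.30 without 36-week replicate 4, and 0.06 without the 3 marked arrays, an alternative added after seeing the data. Its sign thus depended on the normalization and on the arrays kept.

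Between 36 and 4 weeks, miR-214-3p was lower (fitted log2 difference -2.75 ± 0.53 SE, adjusted p = 0.0297) and no miRNA passed as higher. The signal at 4 weeks was at least 1.91-fold higher, a bound set by the high background of 36-week replicate 4 and at least 4.61-fold without that array. Under quantile normalization, with the deposited total signal and with normexp the difference was -1.36, -2.06 and -0.14, and did not pass. The call was lost in 12 of the 16 fits that left out 1 array, namely 4-week replicates 1, 2 and 3, 8-week replicate 2 and each array of 36 or 58 weeks. Next came miR-181b-5p, detected on 2 of 4 arrays at 4 weeks and on no array at 36 weeks. It was at least 1.45-fold higher at 4 weeks (0.955-fold to 3.54-fold with 1 of the 36-week arrays left out, adjusted p = 0.137). It was followed by miR-199a-3p (log2 difference -2.37, adjusted p = 0.137), miR-140-3p (-2.68, adjusted p = 0.342) and miR-140-5p (-2.31, adjusted p = 0.451), and none of these miRNAs passed. Without 36-week replicate 4, on which both lay at the floor, miR-140-3p differed by -1.79 and miR-140-5p by -1.78, and without 36-week replicate 3 miR-140-3p differed by -3.41. Without 4-week replicate 4 miR-181b-5p passed (adjusted p = 0.00647). These ages lay on different slides.

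Between 58 and 4 weeks, the widest span of age, miR-214-3p was again the 1 miRNA that passed (fitted log2 difference -2.86 ± 0.53 SE, adjusted p = 0.0199), with a signal at least 3.16-fold higher at 4 weeks. Under quantile normalization, with the deposited total signal and with normexp this difference was -1.26, -2.06 and -0.03, and did not pass. Signals of miR-375-3p, detected on 2 of 4 arrays at 4 weeks and on 4 of 4 at 58 weeks, were 4.16 ± 0.71 (SD, n = 4) and 6.65 ± 0.22. The log2 difference of 2.49 ± 0.61 (SE) did not pass (adjusted p = 0.114). Nor did miR-199a-3p (-2.42, adjusted p = 0.114), miR-181b-5p (at least 2.30-fold higher at 4 weeks, where 2 of 4 arrays detected it, adjusted p = 0.131) or miR-140-3p (-2.72, adjusted p = 0.247). Of these, miR-375-3p passed without 8-week replicate 4 (adjusted p = 0.0378), miR-181b-5p without 4-week replicate 4 (adjusted p = 0.00917), and miR-199a-3p and miR-140-3p without 36-week replicate 4 (adjusted p = 0.0245 and 0.0125). The median difference over the tested miRNAs was -0.0031, and -0.95 with no scaling between arrays. With 1 array left out it ran from -0.43 (without 4-week replicate 2) to 0.32 (without 4-week replicate 1). The call of miR-214-3p was lost in 6 of the 16 fits that left out 1 array, namely 4-week replicates 2 and 3 and each array of 58 weeks, and age and slide cannot be told apart here.

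Of the 12 lists tested between 58 and 4 weeks, 3 passed camera as higher at 58 weeks, and none passed with an estimated correlation or with fry. The epithelial, gut and pancreas list (adjusted p = 0.000731) had 4 of 4 tested members higher, led by miR-375-3p, with miR-205-5p at 0.82, miR-192-5p at 0.70 and miR-215-5p at 0.66 on the log2 scale. Its adjusted p = 0.192 with an estimated correlation. The leukocyte list (adjusted p = 0.00792) had 5 of 6 members higher, among them miR-146a-5p at 2.21, miR-142a-3p at 0.98 and miR-342-3p at 0.93, with miR-181a-5p at least 1.64-fold lower. Its adjusted p = 0.192 with an estimated correlation. The ageing, senescence and inflammation list (adjusted p = 0.0210) had 8 of 11 members higher, with miR-29b-3p at 1.89 and miR-497a-5p at -1.14, and shares 2 tested members with the leukocyte list. Its adjusted p = 0.762 with an estimated correlation. Without the 2 arrays of highest background, an alternative added after seeing the data, 0 lists passed.

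The other lists did not pass between 58 and 4 weeks. Adjusted p was 0.117 for the miR-29 and miR-30 families (5 of 8 higher), 0.284 for platelet and endothelial miRNAs (8 of 9 higher), 0.446 for the miR-17 cluster and its paralogs (3 of 7), and 0.497 each for erythrocyte (2 of 6), brain (2 of 3), let-7 (3 of 7) and late miRBase miRNAs (58 of 110). It was 0.553 for the Sfmbt2 cluster (2 of 4) and 0.903 for striated muscle (2 of 3). Adjusted over the list alone, 1 platelet and endothelial member passed, miR-199a-3p (adjusted p = 0.0108), and 1 epithelial member, miR-375-3p (adjusted p = 0.00388), while 0 members passed in the other lists. Over all tested miRNAs 0 members of any list passed. The liver and Dlk1-Dio3 lists had 2 tested members each and the testis list 0, too few to test.

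Between 8 and 4 weeks 0 of 12 lists passed by camera, with an estimated correlation or by fry (0 with an unadjusted camera p under 0.05). Between 58 and 8 weeks 0 of 12 passed by each of these tests (2 with an unadjusted camera p under 0.05, leukocyte and epithelial, at adjusted p of 0.202 and 0.111). Adjusted over the list alone, miR-142a-3p of the leukocyte list (adjusted p = 0.0319) and miR-34a-5p of the ageing list (adjusted p = 0.0185) passed between 58 and 8 weeks. These ages lay on different slides, so age and slide cannot be told apart here.

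Between 36 and 8 weeks 0 of 285 miRNAs passed (limma, 85 with an unadjusted p under 0.05, 77 of them higher at 36 weeks), on different slides. The 85 depended on single arrays: it was 9, 12 and 23 without 8-week replicates 1, 2 and 4, 55 and 47 without 4-week replicates 3 and 4, 133, 45 and 19 without 36-week replicates 1, 3 and 4, and 49 without 58-week replicate 4. It was 25 with the total signal, 24 with normexp and 193 with array weights. The median difference over the tested miRNAs was 0.71, and -0.32 under quantile normalization. It was 0.24 without 36-week replicate 4, and 1.21, 1.30 and 1.33 without 8-week replicates 1, 2 and 4. The smallest p were those of miR-34a-5p (log2 difference 1.61), miR-7020-5p, miR-214-3p, miR-5622-3p and miR-30b-5p (1.56), each with an adjusted p of 0.151. At 36 weeks miR-7020-5p, miR-214-3p and miR-5622-3p were detected on no array, and their bounds lay under 1-fold, so no size is given. The difference of miR-30b-5p was 0.45 without 36-week replicate 4 and -0.19 under quantile normalization, where that of miR-34a-5p was 0.15. Between 58 and 8 weeks 0 passed (limma, 15 with an unadjusted p under 0.05). The smallest p were those of miR-34a-5p (1.64), miR-7020-5p (at least 1.24-fold higher at 8 weeks, 0.938-fold at the lowest with 1 of the 58-week arrays left out), miR-142a-3p (1.61), miR-214-3p (at least 1.43-fold higher at 8 weeks) and miR-671-5p (-2.14), each with an adjusted p of 0.315. Without 8-week replicate 3 miR-214-3p passed (adjusted p = 0.0361). Under quantile normalization the differences of miR-34a-5p and miR-142a-3p between 58 and 8 weeks were 0.22 and 0.75.

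Between 58 and 36 weeks, on the same slide, 0 of 285 passed (limma, 5 with an unadjusted p under 0.05, all higher at 58 weeks). These were miR-6931-5p (log2 difference 2.42 ± 0.77 SE), miR-375-3p (1.62 ± 0.61), miR-19b-3p (2.10 ± 0.81), miR-146a-5p (1.86 ± 0.80) and miR-5119 (detected on no array at 36 weeks, at least 1.32-fold higher at 58 weeks, 0.967-fold at the lowest with 1 of the 36-week arrays left out), each with an adjusted p of 0.717. Without 36-week replicate 4 miR-6931-5p differed by 1.71, and without 36-week replicate 1 miR-19b-3p differed by 2.82 and miR-146a-5p by 2.47.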

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

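The slide tests of the 4 miRNAs and of the 75th percentile signal, and the test without the 2 arrays of most background, were chosen after the result was seen. Within an age, 1 array stood apart from the other 3 in 8 of 87 groups of values, where chance gives about 4.35. The SD of negative-control spots was 59.3 on 36-week replicate 4 (2.76 to 4.39 on the others) and 3.54 on 8-week replicate 3. On the log2 scale, miR-140-5p was 7.16 on 4-week replicate 1, miR-199b-5p 3.07 on 8-week replicate 4, miR-5622-3p 4.70 on 8-week replicate 3 and miR-5119 3.09 on 8-week replicate 1. At 58 weeks, miR-181b-5p was 2.38 on replicate 1 and miR-671-5p 2.71 on replicate 3, each with the other 3 arrays at the floor.

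The lower signals of miR-214-3p, miR-140-3p, miR-199a-3p and miR-181b-5p at older ages averaged -2.57 on the log2 scale from 4 to 58 weeks, or -2.00 with miR-214-3p and miR-181b-5p, undetected at 58 weeks, at their bounds. Without the 2 arrays with the most background the largest trend p of the 4 was 0.00211 (limma, unadjusted), so the lower signals did not rest on those arrays alone. The 4 were chosen by the trend over these same arrays, so this p is no independent test. A loss of all dim miRNAs is argued against by a median change of -0.0024 (SD 0.50) in 105 other miRNAs, 53 of them lower at 58 weeks. Their 4-week means lay in the range of the 4, from 4.32 to 7.64 on the log2 scale, so the dimmest were not weighed apart. A slide difference stays open: with slide as a block the smallest adjusted p of the 4 was 0.373. Their slopes were -0.83, -0.92, -1.21 and -1.15 with the block, against -0.75, -0.69, -0.56 and -0.53 without. The median difference over the tested miRNAs was also negative within slides (-0.72 for 8 against 4 weeks, -0.52 for 58 against 36 weeks). The slopes with the block may thus hold a shift of most miRNAs, and they do not decide on slide. The step of the 4 from 8 to 36 weeks, -1.05, cannot be told apart from a slide difference. Within slide 1 the 4 were lower at 8 than at 4 weeks by exact permutation (-1.50, p = 0.0286). These miRNAs were chosen by the trend over the same arrays, however, and within slide 2 the difference was -0.02. Age stays among the open explanations.

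Many more miRNAs passed with array weights (177 for 58 against 4 weeks) or without the 3 arrays marked for evaluation (156 for the trend, 97 of them higher with age). With array weights, 12 of the 35 splits of these 8 arrays gave as many calls, up to 238, which points to a structure of the arrays. Without the 3 arrays, an alternative chosen after seeing the data, 2 of 100 splits gave as many trend calls (highest other 160). As a random split gave more calls than the real 156, this share does not exclude chance. With slide as a block 0 of the 156 trend calls were left, but 148 kept their sign, and the median slope in their direction went from 0.53 to 0.43 while its median SE went from 0.17 to 0.61. With 0 left, the prediction written beforehand for a slide difference, that few of the calls would remain, was met. It did not allow for the loss of precision, which was weighed only afterwards. The lost calls thus cannot tell a difference between the slides from a loss of precision, and slide, age and chance stay open.

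The 75th percentile signal was lower at 58 than at 4 weeks by 1.03 on the log2 scale. Labelling efficiency is argued against, since the signal less the labelling spike-ins was still lower (-0.99, exact p = 0.0286). The older age of each slide was lower (mean -0.48, exact p = 0.0114 within slides), which argues against slide as the whole cause. Hybridization or scanning could have contributed, because less the hybridization spike-ins the difference was -0.62 (exact p = 0.0857). A lower miRNA share in serum RNA at older ages was not tested.

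Other splits of the same arrays were counted for each result. For the trend 3 of 100 splits gave as many calls as the real 1 (highest other 173). For 58 against 4 weeks it was 1 of 35 (highest other 0), the smallest share that 35 splits can give. Both shares were under 0.05, but they are not adjusted over the split tests and each rests on 1 miRNA. The splits also moved arrays between the slides, and with slide as a block the trend gave 0. Chance is therefore not excluded for either. For the F test 6 of 100 splits gave as many as 1 (highest other 189) and for 36 against 4 weeks 4 of 35 (highest other 217), so chance cannot be excluded. The split with 217 calls set 4-week replicates 1 and 4 and 36-week replicates 3 and 4 against the rest, which parts arrays by background rather than age. For the lists of 58 against 4 weeks 17 of 35 splits gave as many as 3 (highest other 8). Counts of 0 are reached by any split (35 of 35), so that the splits say nothing about chance for them; the highest other was 11 for 8 against 4 weeks, 2 for 36 against 8 weeks, 0 for 58 against 8 and for 58 against 36 weeks, and for lists 6 for 8 against 4 and 9 for 58 against 8 weeks.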

How the results depend on the processing

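Alternatives scaled on spike-ins, without the 2 arrays of highest background or without the 3 marked arrays were chosen after seeing the data. Counts follow for the F test, the trend, 36 against 4 and 58 against 4 weeks in that order, against 1 each in the report. They were 3, 6, 3 and 3 with no scaling, 0 each with quantile normalization, with the total signal and with only the 24 miRNAs detected on all arrays, and 4, 8, 4 and 4 with the brightest probe. With array weights they were 218, 187, 12 and 177 (the weights' fit stopped before convergence), scaled on spike-ins 2, 4, 3 and 3, and without the 3 marked arrays 14, 156, 7 and 17. Normexp gave 17 for the trend (15 higher, 2 lower) and 0 for 58 against 4 weeks, and neither these 17 nor its 1 for the F test and 1 (higher) for 36 against 4 weeks included miR-214-3p. No detection filter gave 0 for the F test, 2 for 58 against 4 weeks and 1 for 36 against 4 weeks, another miRNA than miR-214-3p (adjusted p = 0.0702). The slide block gave 0 for the F test and 0 for the trend. Without the 2 noisiest arrays the trend gave 3, 36 against 4 weeks 0 and 58 against 4 weeks 2. Adjusting over the 6 pairs together gave 0 for both pairs, and using only the arrays compared gave 0 and 4. Apart from array weights and the 3 marked arrays, weighed above, the cause of these changes was not tested.

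With the replicate number as a block the F test, 36 against 4 and 58 against 4 weeks gave 0 and the trend 1. The numbers gave no sign of pairing the mice: same-numbered deviations had a median correlation of -0.30 (-0.90 to 0.81), against -0.22 for other numbers at other ages. Of 16 arrays 2 correlated best with their own number. As the first principal component followed background, this check cannot exclude a pairing.

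Where the report gives 0, array weights gave 180 for 36 against 8, 193 for 58 against 8 and 43 for 58 against 36 weeks. Without the 3 marked arrays 8 against 4 weeks gave 1, 58 against 8 weeks 6 and 58 against 36 weeks 2, and without the 2 noisiest 58 against 8 weeks gave 4. Lists for 8 against 4 weeks gave 1 with quantile normalization, 2 with normexp and 1 with array weights. Lists for 58 against 8 weeks gave 7 with normexp, 7 with no filter and 6 with the brightest probe. Lists for 58 against 4 weeks (3 in the report) gave 1 with no scaling and 1 scaled on spike-ins, 5 with no filter, and 0 with only miRNAs detected on all arrays, array weights, an estimated correlation, fry, and either set of arrays left out.

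Leaving out 1 array at a time gave 0 to 2 for the F test, 1 to 3 for the trend, 0 to 2 for 36 against 4, 0 to 3 for 58 against 4 and 0 to 1 for 58 against 8 weeks. For lists it gave 0 to 2 for 8 against 4, 1 to 5 for 58 against 4 and 0 to 4 for 58 against 8 weeks. The F test gave 0 in 14 of the 16 omissions, and the trend gave 3 without 36-week replicate 4. The trend of miR-214-3p passed in 26 of 30 alternatives. Among the 26 were all 16 fits that left out 1 array and the 3 alternatives chosen after seeing the data. The trend did not pass with normexp (slope -0.0064 ± 0.033 SE, about 0), quantile normalization (-0.41), total signal (-0.58) or the slide block (adjusted p = 0.373). With normexp the difference of miR-214-3p turned to 0.02 for 36 against 8 and 0.13 for 58 against 8 weeks. As the normexp offset of 50 shrinks differences of dim miRNAs, this alternative does not show the effect of background correction alone. Scaling on the percentile over all miRNAs was not run, because that percentile was -0.15 on 1 array, and with slide as a block the 4 pairs across slides have no value. Dim signals over background limit what could be detected.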

Other observations

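The test of growth miRNAs was fixed before its result was seen. Of 1881 miRNAs on the array, 572 were detected on at least 1 array. Of 43 Dlk1-Dio3 cluster miRNAs on the array 10 were detected, of 25 testis miRNAs 2, and of 20 brain miRNAs 3 (miR-128-3p, miR-212-3p and miR-328-3p). So were 4 of 6 liver, 4 of 9 striated muscle and 8 of 13 epithelial miRNAs, 8 of 8 miR-29 and miR-30 family members and 7 of 9 let-7 family members. The liver miRNA miR-122-5p differed by -0.18 ± 1.39 (SE, log2) between 58 and 4 weeks, and the muscle miRNA miR-1a-3p by -1.41 ± 1.26. The SD of miR-122-5p was 2.37 at 4 weeks and 0.37 at 58 weeks, and that of miR-1a-3p 0.85 and 2.02 (n = 4 each).

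A hypothesis is that the lower miR-214-3p, miR-199a-3p and miR-140-3p may follow the end of skeletal growth, with other miRNAs of growing connective tissue lower too. Of 23 such miRNAs on the array 5 were tested and 11 were detected on no array. Their mean differed by 0.06 between 58 and 4 weeks (exact permutation p = 0.857), with 3 of 5 lower, and by 0.20 with miR-483-5p, undetected at 58 weeks and with a bound under 1-fold, taken as unchanged. The test gave no sign of a shared fall, and 5 members are too few to exclude one.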
